A study of Homo sapiens with 3 samples.

How the data were processed

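CUT&Tag was performed in HepG2 cells without or with H89, with an IgG library from untreated cells, per the labels. HDAC1 is named as the target in the series title only. The 3 samples form 3 groups of 1 library each, and nothing in the labels gives replicates. The submitters' processing notes name Bowtie 0.12.2 and the hg19 build. The peak caller, its control library and its threshold, and any filtering of duplicate or multiply mapping reads, are not given in the sources used here. If reads that map equally well to several places were kept, repeats and alternative haplotypes gain summits, and if local background was not taken from a control library, open or amplified chromatin does.

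The authors deposited 2 tables without a header, one for each HDAC1 library, with a chromosome, a 1-bp interval, a peak name and a score. The peak names match the control and the treated sample titles, and on that basis each table was assigned to its library. No table of the IgG library was used here. Per the file layout, peaks were called on each library separately and only the summit was kept, so peak widths, read counts and fold enrichments were not analysed here. The deposited score is read as a −log10 p-value. This reading rests on the values. A Poisson mean was fitted to the commonest score between 5 and 6, taken as the upper tail of 3 or more counts. It predicted the commonest score at the 5 other steps, from 2 to 7 counts, to within 3.28e-05 in both tables. The steps of that mean hold 41.6% of control and 41.3% of H89 summits, and those of a second mean, fitted in the same way to the commonest remaining score between 4 and 5, hold a further 20.6% in each. The other scores were not fitted. The lowest scores, 2.03 in the control and 2.02 with H89, equal tail probabilities of 0.00937 and 0.00957. The summits are therefore read here as calls without adjustment for multiple testing. The first fitted mean was 0.0269 in the control and 0.0271 with H89, so the same step differs by at most 0.02 between the tables up to step 7. The plan was to rank scores within each list only, since the 2 libraries were not shown to share 1 scale. Scores were nonetheless set side by side here, with differences up to 0.1 treated as equal. The match of the first mean's steps was checked only up to step 7, so higher scores are compared without that check. Neither the tables nor the labels give read totals, so depth is unknown.

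Positions are given 1-based on hg19. The gene table at hand describes GRCh38.p14, another build, so summits were not assigned to genes, promoters or exons. Comparisons of gene sets, of the 15 gene lists fixed before the data were examined and of distances to start sites were therefore not run, and HDAC1 and the PKA subunit genes have no values here. That table was used only for the number of protein-coding genes per chromosome (19122 on the autosomes). Summits were placed in chromosome bands with the hg19 band table of circlize 0.4.16. All 24 of its chromosome lengths equal the hg19 lengths in GenomeInfoDb 1.38.1 (R 4.3.3).

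The planned criterion for a shared peak was an overlap of at least 1 bp. For single-base summits that means the identical base, so a distance of 1000 bp, also set before the data were examined, was used as the main criterion and the identical base as a comparison. One-to-one pairs are mutually nearest summits within 1000 bp. Chance overlap was estimated from 100 random placements of the H89 summits within their chromosomes or bands. Summits named individually follow a rule set before the data were examined. It takes the 10 highest-scoring summits without a partner in each table and the 5 highest shared ones. The rule did not say how to rank shared summits, and pairs were ranked by the mean of their 2 scores. Ratios carry the exact binomial interval of the H89 share, expressed as a ratio. Functions for distances, pairing and score steps were tested on simulated data. In 7000 planted pairs, 99.9% were recovered, and 0.23% of random scores fell on a step by chance. The alternatives were the primary chromosomes only, the summits at or above the median score of each table, merging of summits within 500 bp, other pairing distances, equal numbers of top summits, and higher minimum scores. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.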

Results

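HDAC1 is a class I histone deacetylase, an enzyme that removes acetyl groups from histones as part of corepressor complexes. Its chromatin positions were profiled by CUT&Tag in HepG2, a human hepatocellular carcinoma cell line, without or with H89, a small-molecule inhibitor of the cAMP-dependent kinase PKA. In CUT&Tag, an antibody directs a tagging transposase to chromatin in permeabilised cells, so that sequenced fragments accumulate where the target protein sits. The comparison asks how the HDAC1 binding profile differs with H89. PKA activity itself has no values here. There was 1 HDAC1 library per condition, both titled WT (wild type), and 1 IgG library from untreated cells. The IgG library was not analysed here, so no background measured the same way stands beside the values. The processed data were 2 lists of HDAC1 peak summits on hg19, each summit a single base with a score, read here as the −log10 of a p-value. The control list held 9476 summits and the H89 list 11553. Read depth is unknown. With no replicates, the differences have no replicate check and H89 could not be tested against the control. All intervals are exact (Clopper-Pearson) 95% intervals and cover counting error only. Those of ratios treat the 2 lists as independent, although most summits were shared, so their overlap does not show equal ratios.

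The H89 library held more HDAC1 summits than the control library, and the ratio, though not the difference in number, was larger among high-scoring summits. Over all summits the H89 to control ratio was 1.22 (interval 1.19 to 1.25). At a score of 5 or more there were 3971 control and 5336 H89 summits, a ratio of 1.34 (1.29 to 1.40). At a score of 10 or more there were 615 control and 1143 H89 summits, a ratio of 1.86 (1.68 to 2.05). Of those 1143 H89 summits, 1129 had a control summit of any score within 1000 bp, so few were sites called with H89 alone. At a score of 20 or more there were 65 control and 162 H89 summits, a ratio of 2.49 (1.86 to 3.38). The median score was nearly equal, at 4.77 in the control and 4.76 with H89, while the upper quartile was 5.76 in the control and 6.92 with H89. These values compare 2 libraries, and a difference in library depth or efficiency acts on them in the same way as a difference in occupancy. An equal proportional difference in counts at all sites can also give a ratio that rises with the minimum score. The rise therefore does not show that strong sites differed more.

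**Figure D1:**
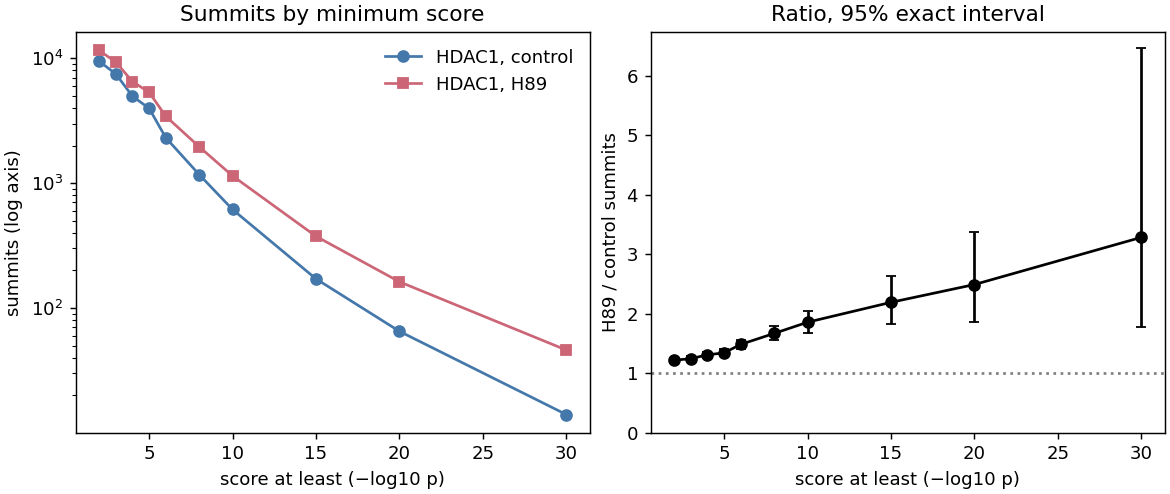
Left, number of HDAC1 summits (log axis) at or above each minimum score (−log10 p) in the control (circles) and H89 (squares) libraries; right, the ratio of H89 to control summits at the same minimum scores, with exact 95% intervals and a dotted line at 1. The ratio was 1.22 over all summits, 1.86 at a score of 10 or more and 2.49 at a score of 20 or more.

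Most HDAC1 sites of untreated cells were also called with H89. Of the control summits, 8303 (87.6%, interval 86.9 to 88.3) had an H89 summit within 1000 bp. Of the H89 summits, 8340 (72.2%, interval 71.4 to 73.0) had a control summit within that distance, which left 1173 control summits and 3213 H89 summits without a partner. When the H89 summits of the primary chromosomes were placed at random within their own chromosome bands, 1.81% of control summits had a partner on average (1.43% to 2.11% over 100 placements), against 87.5% observed on those chromosomes. Placement was uniform within a band and took no account of open chromatin. The contrast therefore does not show that the sharing is particular to HDAC1. Paired summits lay close together, with a median offset of 53 bp.

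Summits found in 1 library alone scored low. The median score was 3.45 for control summits without a partner and 4.77 for those with one, and 3.44 against 5.49 for H89 summits. Only 1 of the 1173 control summits without a partner scored 10 or more, as did 14 of the 3213 H89 summits without one (0.436%, interval 0.238% to 0.730%). Among H89 summits scoring from 2 up to 3, 45.9% had a control partner, whereas among those scoring 20 or more the share was 98.8% (160 of 162). Among control summits the share was 74.9% in the lowest class and 100% (65 of 65, interval 94.5% to 100%) in the highest. Presence in a list is a call against a threshold, so a summit listed once is not shown to be absent from the other library.

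**Figure D2:**
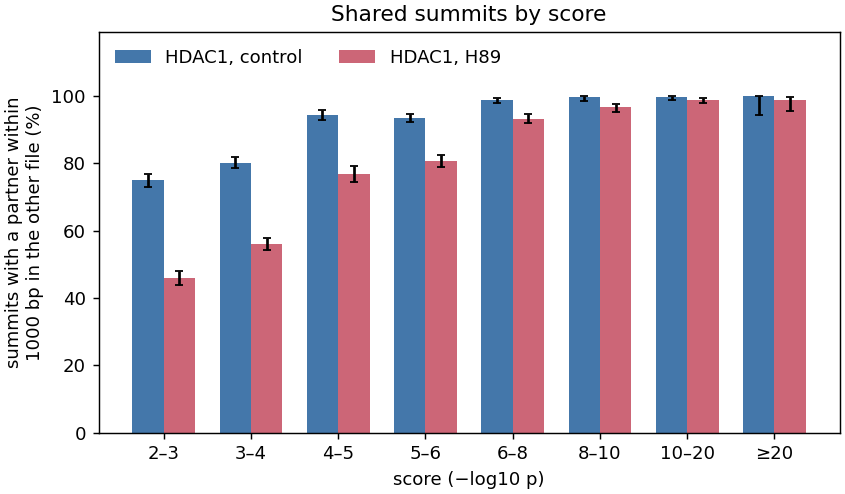
Share of HDAC1 summits (%) with a partner within 1000 bp in the other library, by score class (−log10 p, lower bound included), for the control and H89 libraries; error bars are exact 95% intervals. In the lowest class 74.9% of control and 45.9% of H89 summits had a partner, and in the highest class 100% and 98.8%.

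At sites called in both libraries, the score was more often higher with H89. Of 8189 one-to-one pairs, 4113 (50.2%, interval 49.1 to 51.3) scored higher with H89 by more than 0.1, 1184 (14.5%) scored higher in the control by more than 0.1, and 2892 were within 0.1. The imbalance was larger in higher-scoring pairs. An equal proportional difference in counts at all sites would also give larger score differences at higher scores. The gradient therefore does not show that strong sites differed more. The limit of 0.1 also tied 1349 of 2497 pairs with a mean score from 2 up to 4, but 11 of 105 at 20 or more. Among the 780 pairs with a mean score from 10 up to 20, 74.4% were higher with H89 and 11.7% higher in the control, and the median difference was 2.39. Among the 105 pairs with a mean score of 20 or more, 82.9% were higher with H89 and 6.67% higher in the control, with a median difference of 5.22. Among the 2497 pairs with a mean score from 2 up to 4, 774 were higher with H89 and 374 higher in the control. Their median difference was -0.01, which is the offset between the same score steps of the 2 lists.

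The 5 shared sites with the highest mean score all scored higher with H89, by unequal amounts. The H89 score enters that ranking, which favours sites scoring high with H89. The highest-scoring site of both libraries lay in band 6q27 on chromosome 6, with its summit at position 169240780 in the control (score 76.5) and 169240719 with H89 (score 133.1). The next lay in 20q13.33 on chromosome 20, at 62573492 in the control (50.8) and 62573505 with H89 (87.5). A site in 21q22.3 on chromosome 21 scored 32.9 at 47604530 in the control and 70.4 at 47604509 with H89. In 10p15.3 on chromosome 10, the control summit at 1092925 scored 15.2 and the H89 summit at 1093040 scored 61.0. In 14q11.2 on chromosome 14, both summits fell on base 24584104 and scored 35.3 in the control and 40.5 with H89.

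A few HDAC1 sites called with H89 alone scored 10 or more. The highest, at position 64038684 of chromosome 11 in band 11q13.1, scored 38.0, and the nearest control summit was 13.3 kb away. A site at 133972268 of chromosome 10 in 10q26.3 scored 22.2, with the nearest control summit 91.7 kb away. The other 8 of the 10 highest H89-only summits scored between 10.9 and 13.0 and included sites in 16q24.3 (position 88905645, score 13.0), 1p36.22 (10804580, score 12.3) and 8p23.3 (1845653, score 12.3). The score of 12.3 equals step 6 of the first fitted mean with H89, so these calls may rest on few overlapping fragments. The highest control-only summit, at 88999893 of chromosome 16 in 16q24.3, scored 14.7 and lay 76.6 kb from the nearest H89 summit. The second, at 160555568 of chromosome 6 in 6q25.3, scored 9.94 and lay 155 kb away. Of the 10 highest control-only summits, 5 lay between 1.02 and 1.31 kb from an H89 summit, just outside the pairing distance.

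HDAC1 summits were concentrated in the palely staining chromosome bands, which are known to be gene-rich, in both conditions. Giemsa-negative bands and the palest class of Giemsa-positive bands make up 49.2% of the banded genome and held 77.7% of control and 78.3% of H89 summits on the primary chromosomes. The Giemsa-negative bands held 4.62 control and 5.63 H89 summits per Mb, and the darkest bands 0.686 and 0.808 per Mb. The H89 to control ratio was 1.22 (1.18 to 1.26) in Giemsa-negative bands and 1.18 (1.02 to 1.37) in the darkest bands, with overlapping intervals. In centromeric bands there were 34 control and 31 H89 summits, a ratio of 0.912 (0.542 to 1.53).

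Band 19p13.3, at the tip of the short arm of chromosome 19, held the most HDAC1 summits in both libraries. It had 139 in the control and 190 with H89, which is 20.1 and 27.5 per Mb, a ratio of 1.37 (1.09 to 1.71). Band 16p13.3, where the alpha-globin genes lie, had 103 and 144 summits, a ratio of 1.40 (1.08 to 1.82). Band 17q25.3 had 110 and 134. Band 16p11.2 was an exception among the richest bands, with 89 control and 87 H89 summits (ratio 0.978, interval 0.719 to 1.33). The 10 bands with the most H89 summits held 9.25% of control and 9.27% of H89 summits on 1.72% of the banded genome. The highest ratio among bands with at least 40 summits in both libraries together was 1.90 (1.097 to 3.40) in 5q35.3 at the tip of chromosome 5, from 21 control and 40 H89 summits. Of these 158 bands, 141 held more summits with H89, 6 held fewer and 11 held equal numbers. In none of the 158 did the interval of the ratio exclude 1.22, the ratio over all summits. These intervals treat the 2 lists as independent although most summits were shared, so this does not show that the bands were alike. Bands were named after their values were seen.

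**Figure D3:**
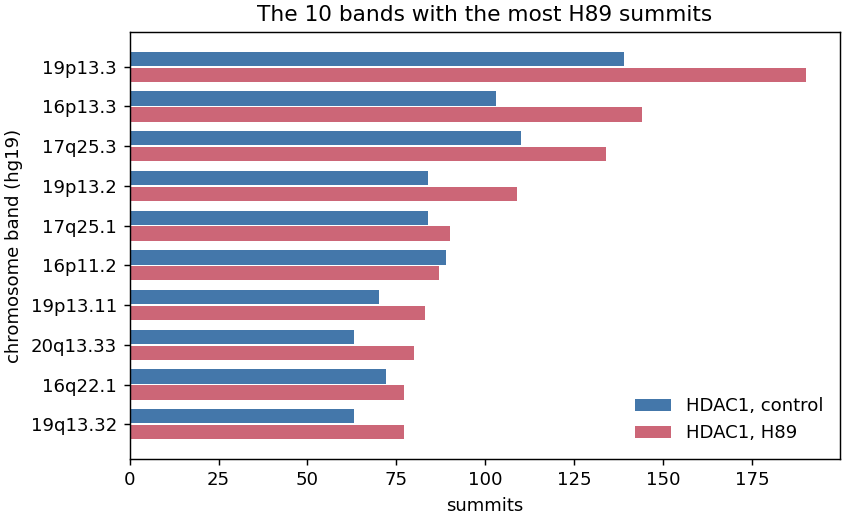
Number of HDAC1 summits in the control and H89 libraries in the 10 chromosome bands (hg19) with the most H89 summits; single libraries, no error bars. Band 19p13.3 held 139 control and 190 H89 summits, and 16p11.2 held 89 and 87.

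Every autosome and chromosome X held more summits with H89, with ratios from 1.15 on chromosomes 6, 20 and 21 to 1.38 on chromosome 18 (104 control and 144 H89 summits, interval 1.07 to 1.80). On chromosomes 4 and 21 the interval included 1. Relative to the number of annotated protein-coding genes, chromosome 20 held the most HDAC1 summits, at 0.814 per gene in the control and 0.935 with H89. Chromosome 16 held 0.724 and 0.849, chromosome 17 held 0.612 and 0.740, chromosome 2 held 0.605 and 0.708, and chromosome 22 held 0.559 and 0.712. Chromosome X held the fewest, 0.150 and 0.202. Chromosome 19, the most gene-dense, held 0.461 and 0.572.

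**Figure D4:**
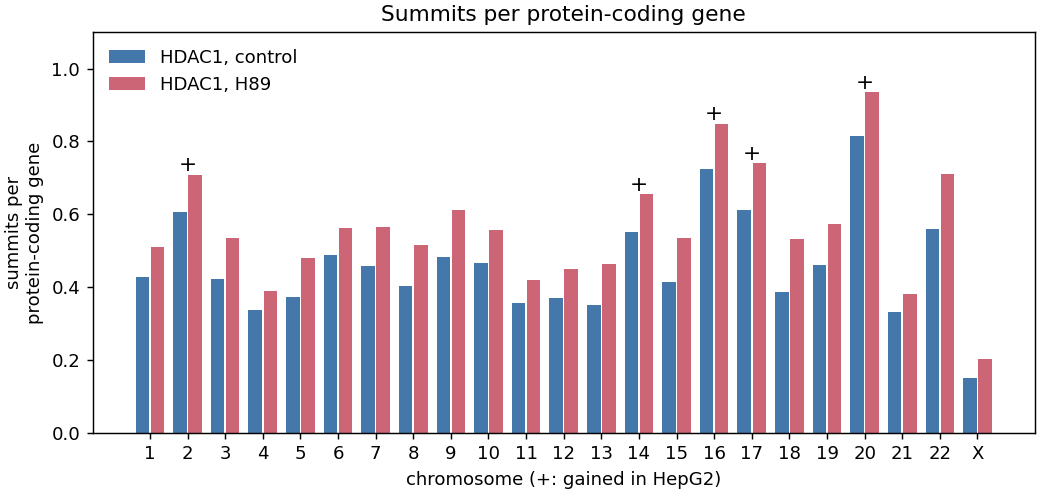
HDAC1 summits per protein-coding gene on each autosome and chromosome X in the control and H89 libraries; plus signs mark chromosomes known to be present in extra copies in HepG2, and single libraries carry no error bars. Chromosome 20 had the highest values, 0.814 and 0.935, and chromosome X the lowest, 0.150 and 0.202.

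The region of the major histocompatibility complex, which encodes antigen-presenting proteins, was counted several times. hg19 carries it on chromosome 6 and again on 7 alternative haplotype contigs. These 7 contigs held 224 control and 318 H89 summits (2.36% and 2.75% of the lists), a ratio of 1.42 (1.19 to 1.69). Bands 6p21.33 and 6p21.32 of chromosome 6, which may not cover the whole region, held 41 and 56, a ratio of 1.37 (0.897 to 2.10). The neighbouring band 6p22.1 held 27 and 25, a ratio of 0.926 (0.515 to 1.66). Without any of the 21 contigs outside the primary chromosomes, 9220 control and 11204 H89 summits remained and the ratio was 1.22.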

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

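The H89 to control ratio of summits was 1.22 on the primary chromosomes alone and with summits within 500 bp merged. At minimum scores chosen after seeing the data it was 1.34 (5 or more), 1.86 (10 or more, which left 615 control and 1143 H89 summits) and 2.49 (20 or more). Keeping the summits at or above the median score of each list left 4779 and 6277, a ratio of 1.31, which says nothing about stability: a median of each list's own fixes the ratio near that of all summits, and ties at the median account for the rest. The share of summits with a partner depended on the distance. For control summits it was 1.49% when the same base was required (a reciprocal overlap of 50% is the same criterion for 1-bp intervals), 61.2% within 100 bp, 84.8% within 500 bp and 89.4% within 2000 bp. For H89 summits it was 1.22%, 50.2%, 69.6% and 74.7%. With the 4738 top summits of each list, the shares were 73.4% in the control and 73.4% with H89, nearly equal by construction, since partners are nearly one-to-one. The share of pairs higher with H89 was 52.7% within 100 bp. Distances other than 1000 bp and the same base were chosen after seeing the data. Of the 13 alternatives set before the data were examined, 7 that need genes or start sites on hg19 were not run. No paired analysis was possible because there is 1 library per condition. Unknown depth and the single library per condition limit all of these values.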

Other observations

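All tests in this part were chosen after the values they concern had been seen.

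Chromosomes 2, 14, 16, 17 and 20, which HepG2 is known to carry in extra copies, held more HDAC1 summits per protein-coding gene than the other autosomes. In the control library the 5 chromosomes ranged from 0.552 to 0.814 summits per gene and took ranks 1, 2, 3, 4 and 6 of 22. The other 17 ranged from 0.331 to 0.559, chromosome 22 being the only one above chromosome 14. The mean difference was 0.67 on the log2 scale, 1.59-fold (exact permutation test over all 26334 choices of 5 autosomes, two-sided p = 7.6e-05, adjusted p = 0.000171 over 9 tests in this family). With H89 it was 0.59, 1.51-fold (exact permutation p = 0.000114, adjusted 0.000171). A candidate explanation is DNA copy number: more template gives more fragments, and more sites then pass a threshold on the p-value. Gene density is argued against as the whole cause, since after a line on genes per Mb the control difference was still 0.58 (exact permutation p = 7.6e-05, adjusted 0.000171) and the gene-densest chromosome, 19, ranked 10. Gene expression or HDAC1 occupancy that differs between these chromosomes stays open as an untested biological explanation, as does whether a control library was used to correct local background.

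The H89 to control ratio of pooled summits was 1.18 (1.12 to 1.24) on the gained chromosomes and 1.23 (1.19 to 1.27) on the other autosomes, with overlapping intervals. The means over single chromosomes were 1.18 and 1.24 (exact permutation test across chromosomes, two-sided p = 0.0456, adjusted p = 0.0456 over the same 9 tests). This p describes the chromosomes of 1 pair of libraries and does not test H89 against the control. Single chromosomes ranged from 1.15 to 1.21 among the gained and from 1.15 to 1.38 among the others.

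The larger number of summits in the H89 library has technical and biological candidate explanations. Extra calls near the score threshold stay open, since only 14 of the 3213 H89 summits without a partner scored 10 or more. The ratio of 1.86 (1.68 to 2.05) among summits scoring 10 or more does not argue against them. Of those 1143 H89 summits, 1129 had a control partner, so that ratio concerns mainly sites called in both libraries. Summits on haplotype and unplaced contigs (256 control and 349 H89) were too few to account for the larger number. Without them the ratio was 1.22 (1.18 to 1.25) on the primary chromosomes. This does not test reads shared with those contigs that were placed on the primary chromosomes. A difference in library size cannot be told apart from H89 treatment: the background mean fitted to the scores was 1.01 times as high with H89 as in the control, but whether that mean comes from the HDAC1 libraries or from a scaled control library is not known. A difference in tagmentation efficiency and a treatment effect on HDAC1 occupancy both stay open, because each condition has 1 library. No band with enough summits had a ratio interval that excluded the ratio of all summits. That does not decide for a general difference, because the intervals treat the 2 lists as independent although most summits were shared.

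Scores took few distinct values, 321 in the control and 393 with H89. Of the control summits, 41.6% (interval 40.6 to 42.6) lay within 0.001 of a step of −log10 Poisson upper tail probabilities at a single mean of 0.0269, and 41.3% of H89 summits lay on the steps of a mean of 0.0271. For these summits the largest deviation of the predicted steps was 3.28e-05, which is consistent with an unadjusted p-value and argues against a score adjusted for multiple testing. A single constant background for all summits is argued against by the same 41.6%. A second mean, 0.0473 in the control and 0.0477 with H89, predicted its own steps to within 1.52e-05 and held a further 20.6% in each list, so the background may have varied between sites; the remaining scores were not fitted. On the steps of the first mean, 30.4% of control and 28.4% of H89 summits sit at 2 or 3 counts, so many of the calls may rest on very few overlapping fragments. The H89 to control ratio was 1.18 on step 2 (1552 and 1837 summits), 1.09 on step 3 (1332 and 1447) and 1.67 on step 6 (135 and 225).

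A contig known to hold ribosomal DNA repeats, gl000220, had 1 summit in each library, at 7578 with a score of 27.5 in the control and at 7616 with 31.8 with H89. Whether these positions lie within the repeats was not examined, so they are not shown to be ribosomal DNA. On another contig outside the primary chromosomes, gl000195, the highest summit lay at 31092 and scored 31.8 in both libraries. The others there scored 22.2 in the control and 27.0 with H89, 10.2 and 9.08, and 2.97 and 5.49.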
